A study of Gorilla gorilla gorilla with 13 samples.

How the data were processed

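RNA was measured in 13 libraries from cerebral organoids, which are 3-dimensional cultures of brain tissue grown from pluripotent stem cells. The organoids came from 1 gorilla induced pluripotent stem cell line and were taken at week 8 of culture, within 3 days. Per the labels' protocols, cells were sorted by flow cytometry into apical radial glia (aRG, n = 4), basal radial glia (bRG, n = 4), basal intermediate progenitors (bIP, n = 3) and BCL11B-positive neurons (N, n = 2). Radial glia are the neural stem cells of the developing cortex, apical ones anchored at the ventricle and basal ones away from it, and basal intermediate progenitors are their committed daughter cells. RNA of 10000 sorted cells was made into Smart-seq2 libraries, which carry no molecular identifiers, with 12 to 17 cycles of PCR, per the labels' protocols. Nothing in the labels says that libraries of a population came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The antigens of the sort other than BCL11B are not given in the sources used here.

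The authors deposited 2 tables of raw read counts per gene symbol, which were not normalized. The first holds 18137 genes counted on the human build hg38, and the second 60583 named genes counted on the gorilla build gorGor6, a build known only from the table's name. STAR and hg38 are named, without a role or a version, per the submitters' processing notes. The annotation, the counter and the use of strand are not given in the sources used here, so genes that overlap or share sequence with paralogs are uncertain. All 18137 symbols of the hg38 table are also rows of the gorGor6 table, but of 11020 genes with at least 1000 hg38 counts over the 13 libraries, 402 held under 10% of that count there and 280 of them were listed at 0. None of the hg38 symbols found in the RefSeq gorilla table (16328 of them, assembly NHGRI_mGorGor1-v2.1_pri) is placed on X or Y there, so DCX, an X-linked gene, was taken from the gorGor6 table. A gorGor6 row with a blank gene name held 0.0035% to 0.0077% of counts and was left out. The 37 mitochondrially encoded rows of that table were all at 0, so the list of those genes could not be tested. In both tables the columns carry the population and a number, and 1 neuron column bears a number that no neuron label has. It was used as a neuron library without a number and is called the unnumbered neuron library.

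The hg38 table was the main one. Total counts per library were 5464721 to 12524938 in it and 11835004 to 26173260 in the gorGor6 table, and every interval or spread covers these libraries only. Differences were tested with edgeR 4.0.16 (quasi-likelihood F-test, TMM scaling) in R 4.3.3. All 13 libraries entered 1 fit with a mean per population, which shares the spread with the neurons, and 16804 genes passed filterByExpr (minimum count of 10). Calls are Benjamini-Hochberg adjusted p-values under 0.05. Standard errors were computed from the fold change and its F statistic. Levels are CPM, counts scaled to a common library size, after TMM scaling and as mean ± SD. Of 33 gene lists fixed before the data were examined, 32 were tested with camera (limma 3.58.1) at a preset correlation of 0.01 on log2 CPM with a prior count of 2. Each was also tested with an estimated correlation and with fry, and adjusted over the lists. The estimated correlation is stricter, and the text gives its adjusted p beside each list described.

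Named genes followed a rule also fixed before the data were examined. It took the 10 largest rises and 10 largest falls per comparison among called genes with a mean log2 CPM of at least 4, an official symbol and no overlap between the groups. It added 10 identity genes and, for each list described, the members with the smallest p. Genes chosen after their values were seen are named as such. Pairs of libraries of a population differed by 10.6 to 92.4 in chi-square per degree of freedom, so none was counted as a duplicate.

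Alternatives were DESeq2 1.42.0, its size factors inside edgeR, no low-count filter, the gorGor6 table, the replicate number as a block, a fit of only the 2 populations compared, and the removal of each library. The tests were run on simulated data first, with 200 changed genes drawn on the real means, library sizes and dispersions. For bRG against aRG, 77.3% of 66 genes changed 4-fold were recovered, 7.46% of 67 changed 2-fold and none of 67 changed 1.5-fold. For N against bIP, 28.8% of 66 genes changed 4-fold were recovered and none of 67 changed 2-fold, with 1 false call. No genome sequence was used, so positions are not reported here.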

Results

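The 13 libraries sampled 4 sorted populations of gorilla cerebral organoids at week 8, to compare basal radial glia with the other cells of the lineage. Total counts in the hg38 table lay between 5464721 (bRG library 1) and 12524938 (the unnumbered neuron library). Between 16534 (bRG library 3) and 17756 genes (bRG library 2) had a count. The first principal component held 67.2% of the variance of the 1000 most variable genes and separated the radial glia libraries (scores of -51.3 to -17.9) from bIP and N (50.4 to 66.6). The second held 13.7%, and bRG library 3 stood at 67.7 on it while the other 12 libraries lay between -18.3 and 6.58. In that library MALAT1, a nuclear noncoding RNA, took 21.3% of gorGor6 counts, against 6.35% to 10.8% elsewhere. Among the 4 populations 3788 genes differed by edgeR's quasi-likelihood test.

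**Figure D1:**
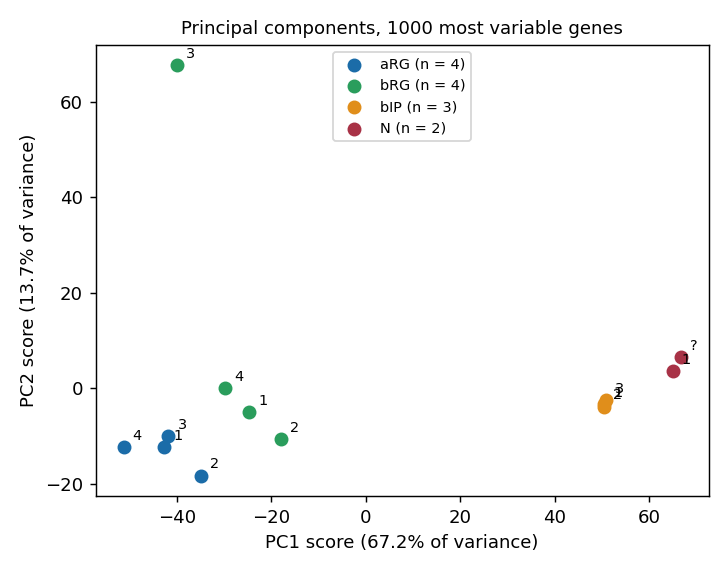
Scores of the 13 libraries on the first (horizontal) and second (vertical) principal components of log2 CPM, coloured by population, with the replicate number beside each point and a question mark for the unnumbered neuron library. Radial glia lie at -51.3 to -17.9 and bIP and N at 50.4 to 66.6 on the first component, and bRG library 3 is alone at 67.7 on the second.

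The first comparison asked how basal radial glia differed from apical radial glia. Genes of mitosis were lower in bRG. Of the 40 tested genes of the G2/M list, 38 fell, with a median log2 fold change of -2.42, and 40 fell when adjusted over the list alone. KIF14, a kinesin of cytokinesis, measured 32.1 ± 8.89 CPM in bRG and 295 ± 102 in aRG (SD, n = 4 each), a log2 fold change of -3.20 (SE 0.319, edgeR adjusted p = 9.75e-05). DEPDC1 (-3.62), TROAP (-3.45), CKAP2L (-3.10), PSRC1 (-3.17) and the spindle gene KIF2C (-2.81) fell as well. So did PIF1 (-3.53), KIF18B (-3.49), CDCA5 (-3.475), CEP55 (-3.35) and MXD3 (-3.15). The calls of PIF1 and CDCA5 ended without bRG library 4 (edgeR adjusted p = 0.0706 and 0.0747). Those of KIF18B and CDCA5 ended without aRG library 4 (0.0641 and 0.0988), and that of KIF18B without bRG library 1 too (0.0542). The proliferation marker MKI67 fell from 1021 ± 319 to 321 ± 94.5 CPM (edgeR adjusted p = 0.011). This call ended without bRG library 4 (adjusted p = 0.0541). The G2/M list was the single list called with an estimated correlation (adjusted p = 0.0057). Its median was -2.25 in the libraries numbered 1 and 2 and -2.56 in those numbered 3 and 4.

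Of the 30 genes of the S phase list, 4 fell and 16 fell when adjusted over the list alone (median -0.72). They were RRM2 (-2.20), CDC45 (-1.40), FEN1 (-1.55) and CDC6 (-1.63), all of DNA replication. The S phase list passed camera, and its adjusted p was 0.0785 with an estimated correlation. Radial glia identity genes were not called different. Of the 17 tested genes of the radial glia list 0 were called and 2 were lower adjusted over the list alone (median -0.259). Camera gave this list an adjusted p of 0.0578, and its adjusted p was 0.497 with an estimated correlation. PAX6 measured 768 ± 219 CPM in bRG and 672 ± 155 in aRG, SOX2 282 ± 77.8 and 393 ± 185, and PROM1 151 ± 87.9 and 145 ± 33.3. HOPX, used as a marker of outer radial glia, measured 65.7 ± 29.1 CPM in bRG and 150 ± 67.4 in aRG, a log2 fold change of -1.19 (SE 0.365, edgeR adjusted p = 0.196). The basal (outer) radial glia list had a median of -0.53 with no member called of 17 by edgeR and 4 lower adjusted over the list alone. It passed camera, and its adjusted p was 0.0866 with an estimated correlation. The basal intermediate progenitor list had a median of 0.62 with no member called of 18 by edgeR. Adjusted over the list alone, 3 were higher. The list passed camera (adjusted p = 5.9e-05) as the 1 list called higher in bRG, and its adjusted p was 0.0866 with an estimated correlation. In it EOMES measured 367 ± 92.9 CPM in bRG and 143 ± 84.4 in aRG (edgeR adjusted p = 0.232). It was called at 0.0465 when the libraries numbered 1 and 2 were separated from those numbered 3 and 4 in the model.

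TTR and COL1A1, markers of non-neural cells, were higher in the aRG libraries. TTR, the transthyretin gene of choroid plexus, measured 4512 ± 2535 CPM in aRG and 628 ± 423 in bRG (log2 fold change -2.85, SE 0.592, edgeR adjusted p = 0.0163). It was 1 of 14 tested genes of the choroid plexus and cortical hem list called (4 adjusted over the list alone), and the adjusted p of the list was 0.497 with an estimated correlation. COL1A1, a fibrillar collagen, fell by 2.28 on the log2 scale and was 1 of 12 mesenchyme genes called, against 5 adjusted over the list alone (adjusted p of the list 0.429 with an estimated correlation). Of 15 immediate early and heat shock genes, HSPB1 (-1.12) and FOS (-1.84) fell, and 7 fell adjusted over the list alone (adjusted p of the list 0.0785 with an estimated correlation). Of 37 ribosomal protein genes, RPL8 (-1.02) and RPS15 (-0.94) fell, and 12 fell adjusted over the list alone (adjusted p of the list 0.119 with an estimated correlation), although ribosomal protein genes have many pseudogenes that can share reads. Of 37 actin and cell protrusion genes, ARHGAP11A (-2.57) and DIAPH3 (-1.88) fell, and 8 fell adjusted over the list alone (adjusted p of the list 0.312 with an estimated correlation).

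In all, 211 genes were called in bRG against aRG, 5 higher and 206 lower in bRG, and 1592 had an unadjusted p under 0.05, 551 of them higher and 1041 lower. SLCO5A1, a transporter-family gene, rose from 117 ± 35.8 to 288 ± 49.3 CPM (log2 fold change 1.30, SE 0.242, edgeR adjusted p = 0.0066). ST18 (1.02), the calcium channel subunit CACNA2D1 (0.91) and CFAP298 (1.10) rose too, though reads of CFAP298 are uncertain where neighbouring transcripts overlap it. The 5th gene called higher, OR10Q1, was at 4.11 ± 1.88 CPM in bRG and 0.254 ± 0.318 in aRG and is named after its values were seen. None of SLCO5A1, ST18, CACNA2D1 and CFAP298 was called in the gorGor6 table, where edgeR called 191 genes lower and none higher and where SLCO5A1 held 9029 counts against 18293 in the hg38 table. Their log2 fold changes there were close to the hg38 ones, at 1.25, 0.93, 0.904 and 1.073, and that table tested 38520 genes. SLCO5A1 stayed called in each removal of an aRG or bRG library, and the calls of the other 3 ended in most of them. In the removals that ended them, the log2 fold change was 0.953 to 1.055 for ST18, 0.765 to 0.958 for CACNA2D1 and 0.938 to 1.188 for CFAP298. DESeq2 called 385 genes, and edgeR called 131 without aRG library 4. With the TTR level as a covariate edgeR called none, 1607 genes had an unadjusted p under 0.05, and the median G2/M fold change was -2.35. With the G2/M score as a covariate edgeR called none, 124 genes had an unadjusted p under 0.05, and that median was -0.175. This score is the mean of the same G2/M genes and did not overlap between bRG (5.18 to 5.4) and aRG (7.21 to 8.26). It nearly repeats the grouping, so the loss of calls with it decides nothing.

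**Figure D2:**
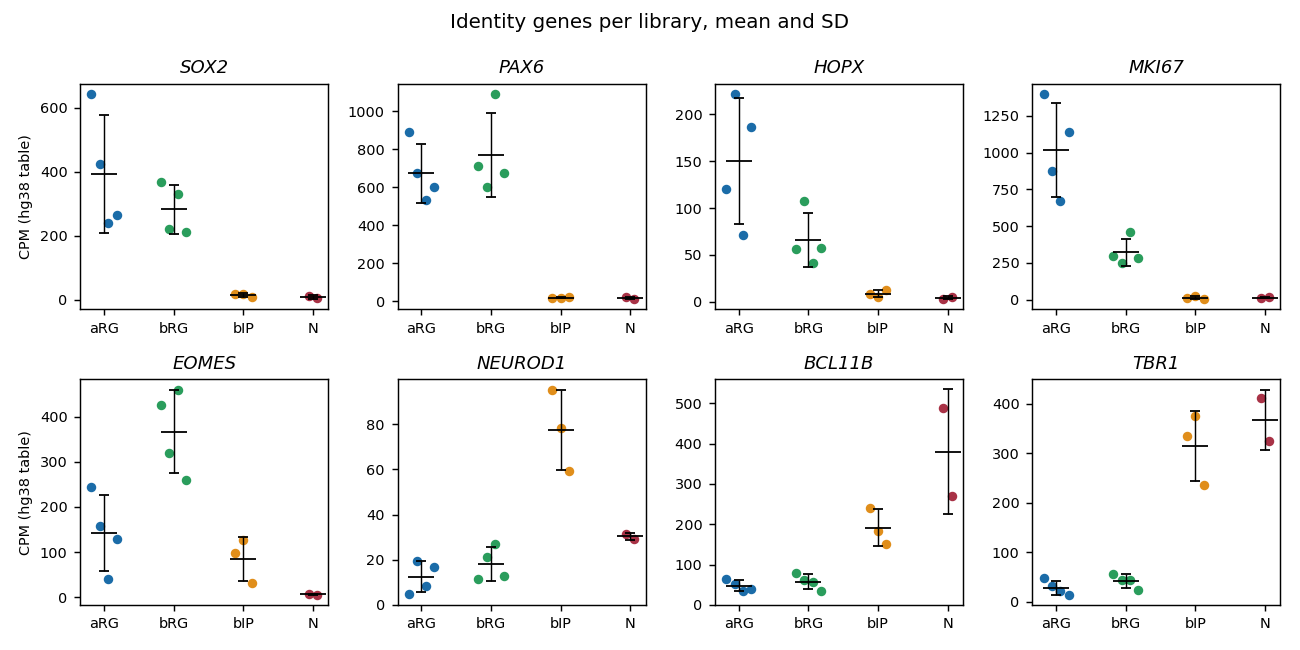
CPM in the hg38 table (vertical axis) of 8 identity genes in each library, by population (horizontal axis), with points for libraries and bars for the mean and SD. EOMES averaged 367 CPM in bRG and 85.3 in bIP, and MKI67 averaged 1021 in aRG, 321 in bRG and 14.0 in bIP.

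Basal intermediate progenitors were set against apical radial glia next. Radial glia genes were lower and neuronal genes higher in bIP. Of 17 radial glia genes 16 fell (17 adjusted over the list alone, median -3.69), and the list was called with an estimated correlation (adjusted p = 0.00638). SLC1A3, a glial glutamate transporter, measured 15.0 ± 3.21 CPM in bIP (n = 3) and 1047 ± 231 in aRG (n = 4), a log2 fold change of -6.12 (SE 0.378, edgeR adjusted p = 2.52e-08). SOX2 (-4.78), PAX6 (-5.22), HOPX (-4.10) and PROM1 (-4.11) fell as well. Of 11 glutamatergic neuron genes 10 rose (10 adjusted over the list alone, median 2.24, adjusted p of the list 0.00717 with an estimated correlation), among them the receptor subunit GRIA2 (3.80) and NEUROD6 (2.28). Of 16 pan-neuronal genes 13 rose (15 adjusted over the list alone, median 1.76, adjusted p of the list 0.0138 with an estimated correlation), among them CAMK2B (3.30) and MAPT (2.67). TBR1, a transcription factor of deep-layer neurons, rose from 28.5 ± 14.1 to 315 ± 71.3 CPM, and BCL11B from 47.8 ± 13 to 191 ± 45.8. DCX, read in the gorGor6 table, rose by a log2 fold change of 2.35.

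EOMES, the usual marker of intermediate progenitors, measured 85.3 ± 49.1 CPM in bIP and 143 ± 84.4 in aRG, and the difference was not called (edgeR adjusted p = 0.345). The intermediate progenitor list held 2 rises and 2 falls among 18 genes (2 and 2 adjusted over the list alone), and its adjusted p was 0.626 with an estimated correlation. Cell cycle genes fell: 39 of 40 of the G2/M list (40 adjusted over the list alone, median -4.58) and 27 of 30 of the S phase list (28 adjusted over the list alone, median -2.56), with adjusted p of 0.00638 and 0.00717 with an estimated correlation. MKI67 measured 14.0 ± 8.94 CPM in bIP and 13.5 ± 2.13 in N. The G2/M score, a mean log2 CPM of the list, was 3.22 to 3.37 in bIP and 3.01 to 3.07 in N. The pan-neuronal score was 8.09 to 8.14 in bIP, 8.48 to 8.5 in N and 5.89 to 6.6 in aRG. By these scores the bIP libraries lay near the neurons. Genes of Cajal-Retzius neurons, early-born RELN-secreting cells of the cortical surface, were higher in bIP. Of 10 such genes 7 rose (9 adjusted over the list alone, median 2.54, adjusted p of the list 0.0279 with an estimated correlation). RELN measured 2048 ± 1001 CPM in bIP and 38.6 ± 22.7 in aRG (log2 fold change 5.73, SE 0.487, edgeR adjusted p = 2.31e-07), and LHX5 (5.36), LHX1 (4.28) and CALB2 (3.78) rose too. CALB2 was not particular to bIP, at 122 ± 34.9 CPM there and 143 ± 8.43 in N. Wnt pathway genes fell in 10 of 17 cases (10 adjusted over the list alone), with TCF7L1 at -4.01 and SFRP1 at -5.37 (adjusted p of the list 0.00638 with an estimated correlation). Notch pathway genes fell in 8 of 18 (9 adjusted over the list alone), with NOTCH3 at -4.01 and NOTCH1 at -2.84, while the ligand JAG2 rose by 2.05 (adjusted p of the list 0.0158 with an estimated correlation). Matrix and integrin genes fell in 13 of 26 and rose in 3 (15 and 3 adjusted over the list alone), with LAMA1 at -3.55 and BCAN at -4.78 (adjusted p of the list 0.00638 with an estimated correlation). Choroid plexus and cortical hem genes were lower in 8 of 14 cases (8 adjusted over the list alone), with TTR at -4.89, and the adjusted p of the list was 0.313 with an estimated correlation. Mesenchyme genes were lower in 4 of 12 cases and higher in 1 (5 and 1 adjusted over the list alone, adjusted p of the list 0.39 with an estimated correlation). In all 3100 genes were called by edgeR, 1423 higher and 1677 lower in bIP, and limma with a quality weight per library called 4813.

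Against basal radial glia, radial glia genes were again lower in bIP. Of 17 radial glia genes 16 fell (16 adjusted over the list alone, median -3.02, adjusted p of the list 0.00783 with an estimated correlation), with PAX6 at -5.41 and GLI3 at -4.54. Of the basal (outer) radial glia list 8 of 17 fell (8 adjusted over the list alone), among them BMP7 (-3.12), MOXD1 (-3.58) and PTN (-3.14), with an adjusted p of 0.00948 with an estimated correlation. EOMES was lower in bIP than in bRG, at 85.3 ± 49.1 (n = 3) against 367 ± 92.9 CPM (n = 4), a log2 fold change of -2.11 (SE 0.498, edgeR adjusted p = 0.00617). In the intermediate progenitor list 7 of 18 genes fell and 1 rose (9 and 1 adjusted over the list alone), and DLL1 (-1.52) and NEUROD4 (-3.31) were among the falls. Its adjusted p was 0.0908 with an estimated correlation. NEUROD1 went the other way, from 18 ± 7.43 to 77.6 ± 17.8 CPM (log2 fold change 2.11, SE 0.412, edgeR adjusted p = 0.00143).

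Of 20 microtubule and neuronal migration genes 13 rose (16 adjusted over the list alone), with CDK5R1 at 2.01 and TUBB2A at 2.10 (adjusted p of the list 0.00948 with an estimated correlation). Of 10 Cajal-Retzius genes 7 rose (7 adjusted over the list alone, median 2.77, adjusted p of the list 0.0275 with an estimated correlation), with RELN at 45.8 ± 20.4 CPM in bRG. G2/M genes fell in 32 of 40 cases (33 adjusted over the list alone) and S phase genes in 22 of 30 (24 adjusted over the list alone), with adjusted p of 0.0275 and 0.0177 with an estimated correlation. Choroid plexus and cortical hem genes were lower in 4 of 14 cases (4 adjusted over the list alone, adjusted p of the list 0.55 with an estimated correlation), with TTR at -2.04. In all 2804 genes were called, 1386 higher and 1418 lower in bIP.

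**Figure D3:**
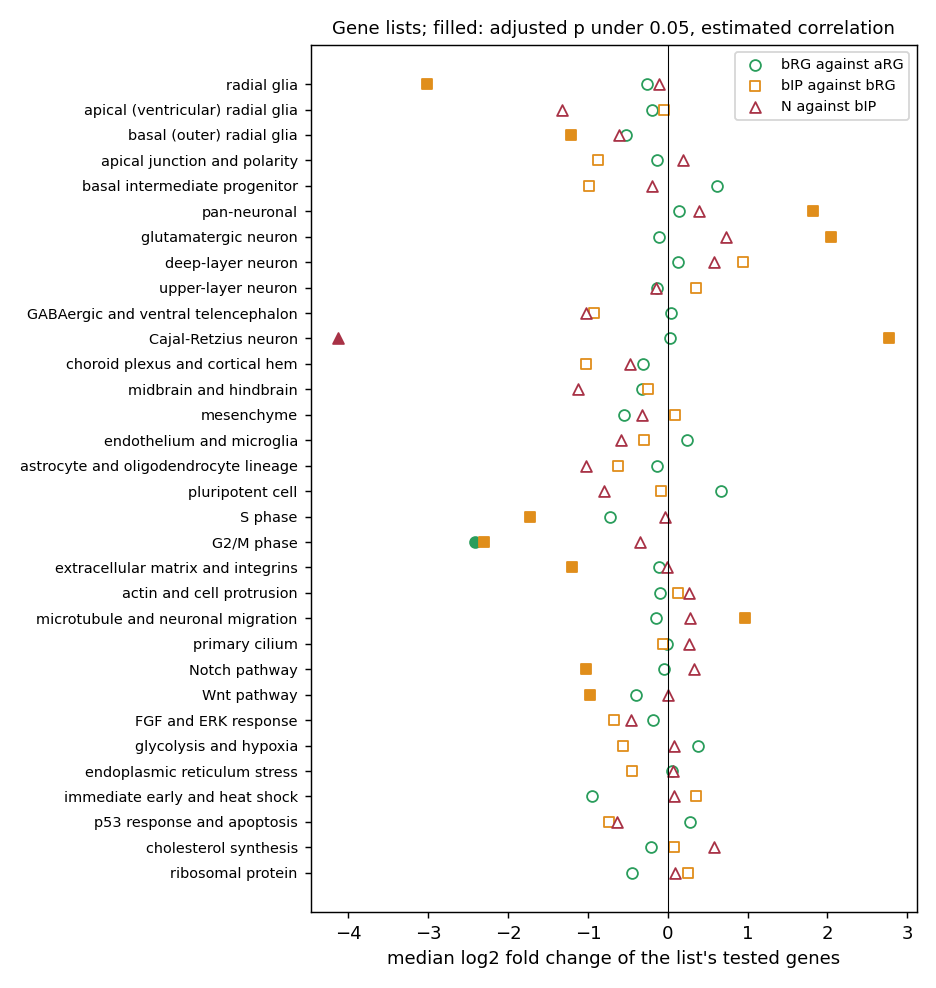
Median log2 fold change (horizontal axis) of the tested genes of each of 32 lists (vertical axis) in bRG against aRG, bIP against bRG and N against bIP, with filled symbols where the adjusted p with an estimated correlation was under 0.05. The G2/M list stands at -2.42 in bRG against aRG, and the Cajal-Retzius list at 2.77 in bIP against bRG and -4.13 in N against bIP.

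Neurons were compared with basal intermediate progenitors next. Cajal-Retzius genes were lower in N: 4 of 10 fell and 8 fell when adjusted over the list alone (median -4.13). Camera called 17 lists at its preset correlation, and the Cajal-Retzius list was the single list called with an estimated correlation (adjusted p = 0.0165). RELN measured 64.1 ± 12.9 CPM in N (n = 2) and 2048 ± 1001 in bIP (n = 3), a log2 fold change of -5.00 (SE 0.638, edgeR adjusted p = 0.00297). TP73, a transcription factor of Cajal-Retzius cells, measured 2.50 ± 2.35 and 71.1 ± 31.4 CPM, but its adjusted p was 0.995 in the gorGor6 table, which holds 123 counts of it against 2455 in the hg38 table. The chemokine receptor CXCR4 (-5.23), LHX5 (-4.14), EPHA3 (-3.44), CXXC4 (-4.26), FAT1 (-3.38) and EOMES (-3.77, at 6.26 ± 0.677 CPM in N) fell too. The calls of LHX5 and EOMES ended without bIP library 1 (edgeR adjusted p = 0.0684 and 0.102) and without bIP library 2 (0.0772 and 0.137). BCL11B, the antigen of the neuron sort, measured 380 ± 154 CPM in N and 191 ± 45.8 in bIP and was not called (edgeR adjusted p = 0.557). TBR1 measured 368 ± 60.6 and 315 ± 71.3 CPM, and MKI67 13.5 ± 2.13 and 14.0 ± 8.94. All 19 genes called by edgeR were lower in N, and 1115 genes had an unadjusted p under 0.05, 348 of them higher in N. DESeq2 called 172 genes, 3 of them higher in N. After the data were seen, limma with a quality weight per library called 103, 48 of them higher in N, and edgeR without bRG library 3 called 70, 2 of them higher. A fit of only these 2 populations called 48, 1 of them higher. The edgeR count was 12, 10 and 33 without bIP library 1, 2 and 3, it was 2 without neuron library 1, and without the unnumbered one no gene was called and 546 had an unadjusted p under 0.05.

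Neurons were set against basal radial glia next. All 17 radial glia genes fell (17 adjusted over the list alone, median -3.69, adjusted p of the list 0.0134 with an estimated correlation). EOMES fell from 367 ± 92.9 to 6.26 ± 0.677 CPM. Of 12 deep-layer neuron genes 7 rose and 2 fell, as they did adjusted over the list alone (adjusted p of the list 0.0537 with an estimated correlation), with TBR1 at 3.14 and BCL11B at 2.72. BCL11B is the antigen of the neuron sort, so its rise is not independent of the sort. GRIA2, a glutamate receptor subunit, rose from 81.6 ± 30.2 to 1727 ± 160 CPM (log2 fold change 4.41, SE 0.431, edgeR adjusted p = 2.04e-06). The calcium channel gene CACNA1E (4.70), CAMKV (5.01) and the potassium channel gene KCNH3 (4.51) rose too. Of 16 FGF and ERK response genes 7 fell and 1 rose (8 and 1 adjusted over the list alone), with FGFR3 at -2.75 and ETV5 at -5.44 (adjusted p of the list 0.0293 with an estimated correlation). Among markers of other cell types, choroid plexus and cortical hem genes were lower in N in 6 of 14 cases (6 adjusted over the list alone, median -1.58, adjusted p of the list 0.301 with an estimated correlation), and OTX2 of that list measured 0.216 ± 0.0414 CPM in N and 17.7 ± 4.79 in bRG. Mesenchyme genes were lower in 2 of 12 (3 adjusted over the list alone, adjusted p of the list 0.415 with an estimated correlation). In all edgeR called 3321 genes, 1787 higher and 1534 lower in N, and the count was 1956 without neuron library 1, 1698 without the unnumbered one and 2027 in a fit of only these 2 populations.

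Neurons were last set against apical radial glia. All 17 radial glia genes fell (17 adjusted over the list alone, median -4.08, adjusted p of the list 0.0116 with an estimated correlation), and so did 38 of 40 G2/M genes (40 adjusted over the list alone, median -4.89, adjusted p of the list 0.0116 with an estimated correlation). Deep-layer neuron genes rose in 7 of 12 cases and fell in 2 (7 and 2 adjusted over the list alone), with TBR1 at 3.70 and SOX5 at 2.13 (adjusted p of the list 0.0418 with an estimated correlation). This list holds BCL11B, the antigen of the neuron sort, so it is not independent of the sort. PLXND1, a semaphorin receptor, rose from 11 ± 3.56 to 263 ± 7.36 CPM, and the synapsin gene SYN2 from 2.48 ± 2.09 to 58.2 ± 1.88. Wnt pathway genes fell in 8 of 17 (10 adjusted over the list alone), among them TCF7L1 (-4.19) and FZD8 (-5.32), with an adjusted p of 0.0116 with an estimated correlation. NEUROD1 measured 30.3 ± 1.69 CPM in N and 12.4 ± 6.90 in aRG and was not called (edgeR adjusted p = 0.0553). Among markers of other cell types, choroid plexus and cortical hem genes were lower in N in 8 of 14 cases (8 adjusted over the list alone, median -3.28, adjusted p of the list 0.202 with an estimated correlation), with TTR at 179.7 ± 155 CPM in N and 4512 ± 2535 in aRG. Mesenchyme genes were lower in 6 of 12 (6 lower and 1 higher adjusted over the list alone, median -2.01, adjusted p of the list 0.232 with an estimated correlation). Astrocyte and oligodendrocyte genes were lower in 2 of 9 (5 adjusted over the list alone, adjusted p of the list 0.0319 with an estimated correlation). In all edgeR called 3320 genes, 1745 higher and 1575 lower in N, and the count was 1979 without neuron library 1 and 1903 without the unnumbered one.

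Fold changes in the 2 tables were correlated. Across the 16048 genes tested in both, which are not independent replicates, Pearson's r was 0.949 (N against bIP) to 0.984 (bIP against aRG). Of the hg38 calls among these genes, 86.8% for bRG against aRG and 63.2% for N against bIP were called in the same direction in the gorGor6 table. Of 11020 genes with at least 1000 hg38 counts, 402 held under 10% of that count in the gorGor6 table, TP73 among them, and 280 of these were listed at 0 there, RPS15 among them, so the lack of a gorGor6 call says nothing of them. The median over all genes of that table shifted to -0.374 in N against bRG and -0.288 in N against aRG, whereas the hg38 medians lay within 0.1 of 0, so gorGor6 levels in neurons are relative to that shift.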

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

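The tests of single libraries, of exchanged bIP and bRG labels, of TTR, of the cell cycle, of the Cajal-Retzius list across populations, of genes of 10 to 50 CPM and of the G2/M and radial glia scores of bRG library 3 were chosen after the result was seen. Libraries far from the rest of their population by Dixon's test were found in 16 of 220 groups of values (aRG and bRG, 4 libraries each), and chance gives about 1 in 20. Among the aRG libraries, library 1 had the fewest genes with a count, 17065 in the hg38 table and 37352 in the gorGor6 table, and the most PIF1 (881 CPM). aRG library 4 was highest of the aRG libraries in TROAP (1001 CPM), KIFC1 (227 CPM) and PBK (223 CPM). aRG library 2 was lowest of the aRG libraries in LRP4 (423 CPM) and highest of them in ADAMTS3 (24.4 CPM). bRG library 2 was highest of the bRG libraries in ST18 (67.3 CPM) and in the immediate early and heat shock score (4.31, a mean log2 CPM), and bRG library 4 in the p53 response and apoptosis score (4.91). bRG library 3 was alone on the second principal component (67.7). Among the bRG libraries it was highest in CACNA2D1 (205 CPM), and lowest in TROAP (10.5 CPM), in the astrocyte and oligodendrocyte score (1.48) and in the ribosomal protein score (6.57).

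The distance of bRG library 3 was weighed against technical explanations, and no biological explanation was tested, since the design gives none for 1 library. A bIP or N library under this label is argued against by its radial glia score of 7.95, against at most 4.54 there (SD 0.245), and an aRG library by its G2/M score of 5.18, against at least 7.21 (SD 0.503), while its whole profile did not separate bRG from aRG, at correlations across genes of 0.912 with the other bRG libraries, 0.913 with aRG, 0.853 with bIP and 0.843 with N (a gap under 0.01 was taken as undecided after it was seen). A larger share of nuclear RNA was predicted before to give NEAT1, MEG3, KCNQ1OT1 and SNHG14 a median ratio of 1.5 or more to the other bRG libraries. Their ratios were 0.234 to 1.64, and the median of 1.03 fell short of that bound. The SD of 0.616 over these 4 genes reaches past the bound, so the explanation is left open, although the rule set before took no account of the spread. Fewer distinct molecules stay open: after thinning to 1 total, 169 genes of 10 to 50 CPM in the other bRG libraries were at 3 counts or fewer, against at most 2 in any other aRG or bRG library, but a different profile would empty such genes too, and the measure planned first, genes above 50 CPM at 0 counts, gave 0 in all 8 libraries. Among these genes, the 2009 whose means in aRG, bIP and N lay within 1.5 times of each other were emptied 0.606 times as often as others of the same level (33 against 54.4 expected, 95% Poisson interval 0.417 to 0.852, for counting error only), which neither reaches 1 nor lies below 0.5, the bounds set before this test.

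G2/M genes were lower in bRG than in aRG, and 38 were called lower without bRG library 3 too, which argues against that library as the cause. With the TTR level as a covariate their median was -2.35 (median SE 0.593) against -2.42 (0.352) before, and 0 of 40 were called. The error was larger in that fit, and why the single calls ended was not tested. Choroid plexus RNA as the whole cause is argued against by that median. Camera at its preset correlation still called the list lower (adjusted p = 1.73e-33). The stricter estimated correlation was not run with this covariate, so that p decides nothing. A lower share of cycling cells alone and a difference in cycle phase between the sorted populations both stay open. Above the bIP level G2/M genes stood at 0.256 ± 0.0338 of their mean in bRG and S phase genes at 0.65 ± 0.104, against 1.72 ± 0.734 and 1.31 ± 0.291 in aRG. The test compared the G2/M minus S phase level of each library between bRG and aRG. It gave an exact permutation p of 0.0286 (two-sided, the smallest that 4 against 4 allow). This takes bIP as the level of radial glia out of cycle, which was not measured. The same test on G2/M minus S phase log2 scores, which also gave 0.0286, takes off no background at all.

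The bIP libraries held more Cajal-Retzius RNA than each of the 3 other populations and less EOMES than bRG. An exchange of bIP and bRG labels is argued against by the radial glia list, whose median in bRG against aRG was -0.259 (median SE 0.293), and a single library by the list staying lower in N in all 3 removals of a bIP library. Cajal-Retzius neurons among the cells sorted as bIP are a candidate explanation that these data do not settle, since the list being higher restates the pattern. A further test asked whether its 7 genes called higher in bIP than in aRG and bRG varied together over the bIP libraries. Of these 4 shared 1 order, between the bounds of 2 and 5 set before. CALB2, 1 of the 7, was as high in N (143 ± 8.43 CPM) as in bIP (122 ± 34.9). RELN measured 3050, 2047 and 1048 CPM in bIP libraries 1, 2 and 3, none of the 10 genes is in another list, the sort antigens other than BCL11B are not given in the sources used here, and a bIP state that expresses these genes stays open as untested. Across genes the bIP libraries correlated with N at 0.94 to 0.962, with each other at 0.951 to 0.96 and with bRG at 0.833 to 0.907. Their whole profile thus lay near that of the neurons, and which cells they held was not tested.

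Other splits of the same libraries bear on the counts. For bIP against aRG the real split gave 3100 genes and the highest other 430, and for bIP against bRG 2804 and 1575. The real split was the 1 of 35 with as many genes in each case, the smallest share that 35 splits can give. Chance is argued against there but not excluded, and the splits take the libraries as separate, which the labels do not say. For bRG against aRG 2 of the 35 splits gave at least the real 211 genes, so chance cannot be excluded by the count alone. The other split gave 473 genes and set libraries numbered 1 and 2 against those numbered 3 and 4, which points to a structure of the samples. With that separation as a term 293 genes were called between bRG and aRG in a fit of 12 libraries, without the unnumbered one, and 233 in a fit of the 8 aRG and bRG libraries. Counts of lists do not exclude chance: 9 of 35 splits gave as many as the real 9 for bRG against aRG (highest other 13), 13 of 35 as many as 14 for bIP against aRG (21) and 9 of 35 as many as 15 for bIP against bRG (17).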

How the results depend on the processing

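The quality weights, the covariates, the removal of bRG library 3 from comparisons without bRG, and the separation of libraries numbered 1 and 2 from those numbered 3 and 4 were chosen after the data were seen. No named gene changed direction while called. DESeq2's size factors in edgeR and the absence of a filter left all counts of called genes within 1.5 times the reported ones. For bRG against aRG, DESeq2 called 385 genes. With TTR as a covariate none was called by edgeR (1607 at an unadjusted p under 0.05), and with the G2/M score as a covariate none either (124). The median G2/M fold change went from -2.42 (median SE 0.352) to -2.35 (0.593) with TTR and to -0.175 (1.17) with the G2/M score, which is made of these genes. That score also separated bRG from aRG without overlap, so the fit with it decides nothing. Quality weights gave 4813 genes for bIP against aRG and gave bRG library 3 a weight of 0.145. For N against bIP the count was 172 with DESeq2, 103 with quality weights (48 of them higher in N), 70 without bRG library 3 and 48 with only these 2 populations. For N against bRG it was 2027 with only these 2 populations. The cause of these differences was not tested.

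Leaving out each library of the 2 populations compared in turn gave 131 to 240 genes for bRG against aRG (lowest without aRG library 4), 2250 to 2847 for bIP against aRG and 1932 to 3090 for bIP against bRG. It gave 0 to 33 for N against bIP, 1698 to 4500 for N against bRG and 1903 to 3003 for N against aRG. A lone neuron library was assumed to vary like the other populations. Over the 4 populations, leaving out any library, the count was 2966 to 4935. For gene lists the range was 7 to 15 for bRG against aRG, highest without bRG library 3, 5 to 18 for N against bIP, 17 to 25 for N against bRG and 19 to 21 for N against aRG. With an estimated correlation 1 list of the 9 was called for bRG against aRG, 1 of the 17 for N against bIP, 11 of the 22 for N against bRG and 13 of the 20 for N against aRG. Fry called 3 for N against bIP, and the G2/M covariate left 2 for bRG against aRG. The first component held 75.6% with 500 genes, 39.5% with all tested genes and 59.6% in the gorGor6 table.

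Replicate numbers were not used as pairs, since not all same-number pairs correlated over 0.1. Of 10 pairs 5 did (from -0.013 to 0.39), 3 of the 4 aRG and bRG pairs among them. The lowest value was that of aRG library 3 with bRG library 3, and 5 of 11 libraries correlated best with their own number. Such correlations cannot show that libraries of the same number were unrelated, so the main fit may leave out a pairing. With the replicate block, which drops the unnumbered library, the counts were 312 for bRG against aRG, 1 for N against bIP, 1822 for N against bRG and 1988 for N against aRG. A term for numbers 1 and 2 against 3 and 4, in 12 libraries, gave 293 genes for bRG against aRG, 3515 for bIP against aRG and 3172 for bIP against bRG.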

Other observations

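Radial glia libraries differed by their number. In a fit of the 8 aRG and bRG libraries, with population in the model, edgeR called 519 of 16804 genes between libraries numbered 1 and 2 and those numbered 3 and 4, of which 415 were higher in 3 and 4. A fit of 12 libraries of the 4 populations called 1311 of 17200 genes for the same separation. This separation was the 1 of the 35 splits of the aRG and bRG libraries with the most genes (473) and was chosen after that was seen. The adjusted p-values of both fits do not allow for that choice. The genes below were chosen after their values were seen. The lactate dehydrogenase gene LDHA measured 165 ± 48.1 CPM in numbers 1 and 2 and 452 ± 167 in numbers 3 and 4, and the sterol synthesis gene MSMO1 268 ± 61.9 and 904 ± 176. Of 22 glycolysis and hypoxia genes 9 were called, with a list median of 1.04, against 4 of 18 Notch pathway genes and 3 each of 18 cholesterol synthesis, 16 endoplasmic reticulum stress and 11 glutamatergic neuron genes, and no list was tested for enrichment. The neuronal RNA-binding gene ELAVL3 was lower in 3 and 4, at 50.5 ± 9.68 against 135 ± 9.30 CPM, and so was the Wnt antagonist SFRP2, at 17.7 ± 5.14 against 121 ± 86.6.

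Whether a batch is shared by number stays open. It was looked for in bIP libraries, which took no part in choosing the 519 genes, with the prediction set before the values were seen. Across these genes, which are not independent replicates, bIP library 3 minus bIP libraries 1 and 2 correlated at 0.722 with the radial glia difference, the highest of the 3 choices of a single bIP library. The 3 differences sum to 0, and chance makes library 3 the highest in 1 of 3 cases, so this value from 1 library decides nothing. MTRNR2L8, chosen after its values were seen, followed the numbers. It measured 3700 and 4710 CPM in aRG libraries 1 and 2 and 1380 and 2080 in 3 and 4. In bRG it measured 2140 and 1740 against 600 and 496, and in bIP 5150 and 5630 against 781. It is 1 gene picked from many, and in bIP it again rests on 1 library. Total counts in the hg38 table followed the numbers in aRG and bRG too. In aRG and bRG they were 5464721 to 7153514 in numbers 1 and 2 and 9761818 to 10551184 in numbers 3 and 4. In bIP they were 6181720 and 9229757 in libraries 1 and 2 against 10812093 in library 3. Neuron library 1 held 9150566, more than the aRG and bRG libraries numbered 1 and 2. Sequencing depth thus differed by number in aRG and bRG, and whether it bears on the called genes was not tested. The labels give no culture, preparation or sequencing batch. A technical batch and a difference between organoid cultures therefore cannot be told apart here as the source of the called genes.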
